A study of Mus musculus with 12 samples.

How the data were processed

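RNA sequencing was done on oligodendrocytes sorted as GFP-positive and propidium iodide-negative cells from brains of Ndrg1-EGFP mice with floxed Lmna, without (WT) or with (KO) Cre expressed from a Cnp allele. Per the labels' protocols, RNA came from 3 biological replicates of each genotype, and libraries were made with an ultra-low-input kit and read as single ends. The titles number 2 libraries for each biological replicate. The characteristics give the age as postnatal day 60, and the growth protocol gives 8 weeks.

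The values are raw read counts per gene and library, as deposited by the authors. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, fastp, HISAT2, SAMtools 1.4.1, featureCounts and DESeq2 1.38.1, and the genome build was mm10. The parameters, the annotation, the use of strand and the treatment of reads that match several genes are not given in the sources used here. Reads of near-identical genes, such as the Lilr4b and Lilrb4a pair and the Ifi200 family, may have been split or left out. Counts were used without rescaling. The table used here held 2398 complete lines, and 1 line that stopped early was left out. Of the gene identifiers, 2226 matched a symbol in the RefSeq gene table for GRCm38, the assembly also called mm10, and 172 with 0.552% of the counts did not. Coordinates come from that RefSeq table. There were 417 genes with no count in any library. The genes lie on chromosome 1 and on chromosome 10 up to 111.3 Mb, so Lmna, Cnp and sex-linked genes were not analysed here.

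The 2 libraries of each biological replicate were summed. Agreement was checked by a chi-square test over genes with at least 20 counts in the pair. KO was compared with WT in edgeR 4.0.16 under R 4.3.3, with TMM factors between 0.951 and 1.05, filterByExpr, a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05. SE values are the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the TMM factors and refer to the counts in the analysed genes. The common biological coefficient of variation was 0.350. With 3 replicates against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so the tests rest on models that share the spread over genes. Intervals and floors of 3 counts cover counting error only.

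Gene lists were fixed before the data were examined, 25 lists besides the sex-linked genes, of which 23 had a tested member. Another 15 lists were written once the symbols and total counts were known and before any genotype difference was computed. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted within the fixed and within the added lists, and again with an estimated correlation and with fry. Lists with 1 or 2 tested members say little beyond those genes. Genes were named by a rule set before the data were examined. It takes Lmna and Cnp, then up to 12 genes of the largest and 12 of the smallest log2 fold change among those with an adjusted p under 0.05, at least 5 CPM in the higher group and replicates that do not overlap, then up to 4 called members of each list, or its 2 members of highest CPM where fewer than 2 were called. No gene met the rule's part on called genes, so the genes of the lists are given as values, some genes and 1 list are not reported here, and other named genes were chosen after their values were seen.

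The alternatives were other size factors, other filters, DESeq2 1.42.0, limma-voom, a replicate block, other treatments of the 2 libraries of a replicate, and leaving out each replicate. Added after seeing the data were DESeq2 on all 12 libraries, DESeq2 without each replicate, the mean log2 CPM of vascular and matrix genes as a covariate, and set tests of lists with at least 3 tested members. The fits were tested on simulated counts for 1484 genes with 200 changed genes in each of 10 simulations. The edgeR fit of 6 replicates called 0.3 genes on average where none was changed, and the edgeR fit of 12 libraries called 64.9. In those data DESeq2 on 6 replicates called 1.7 on average and 4 at most, and duplicateCorrelation on 12 libraries 2.2 on average and 7 at most. A list of 20 genes shifted by 0.5 on the log2 scale was found by camera in 10 of 10 simulations, and a random list in 0. The simulated genes varied independently of each other. These simulations therefore do not test the preset correlation for lists whose members vary together, such as the leukocyte genes with an estimated correlation of 0.48. Transcript lengths for a check on 1 list are the longest transcript per gene in GENCODE M21.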

Results

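Myelinating oligodendrocytes were isolated from mouse brain by fluorescence-activated sorting of cells that carried the Ndrg1-EGFP reporter and excluded propidium iodide, a dye that enters dead cells. Ndrg1 is a gene used by oligodendrocytes that make myelin. The animals were C57BL/6 mice, aged 60 postnatal days in one field of the labels and 8 weeks in another, with floxed alleles of Lmna, which encodes lamins A and C of the nuclear lamina. Mice with 2 intact copies of Cnp, an oligodendrocyte gene, are called WT here. Mice in which Cre recombinase is expressed from 1 of the Cnp alleles are called KO, so the genotypes differ in Cre and in the number of intact Cnp copies as well as in the recombination of Lmna. Each genotype had 3 biological replicates, and each replicate was represented by 2 libraries, 12 libraries in total. The table analysed here held 2398 genes of chromosomes 1 and 10, the latter up to 111.3 Mb. Lmna, Cnp, the genes of the mitochondrial genome and sex-linked genes are not analysed here, so the recombination of Lmna was not checked and no statement below extends to the rest of the genome. Counts in these genes ranged from 1838676 to 3060812 per library and from 3694551 to 6093336 per biological replicate. These totals cover part of each library and are not its depth.

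Among these genes the most abundant transcripts were those of Sgk1, Csrp1, Tmeff2, Pea15a and Glul. Sgk1, a glucocorticoid-inducible kinase, took 2.69% of the counts on average over the 6 replicates. The 10 most abundant genes took between 15.7% and 20.1% of the counts of a replicate. The 2 libraries of a replicate differed by little more than sampling noise. A chi-square test over genes gave p values from 0.0594 to 0.486 for the 6 pairs of libraries, with a chi-square between 1.00 and 1.06 per degree of freedom. Summed over the 6 pairs the chi-square was 8438 on 8091 degrees of freedom (chi-square p = 0.00353), a small excess over sampling noise. Pairs of different replicates of a genotype gave 38.1 to 140 per degree of freedom. The libraries of a replicate were therefore summed and counted as 1 sample, giving n = 3 for each genotype. Expression is given in CPM, the count of a gene scaled to a fixed total over the genes of the table.

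The comparison of KO with WT asked which transcripts differ between myelinating oligodendrocytes of the KO and WT genotypes. The genes with the smallest p included Adamts4, a protease made by myelinating oligodendrocytes, and Pdxk, pyridoxal kinase, which makes the active form of vitamin B6. Adamts4 stood at 6582 ± 489 CPM in WT and 9388 ± 394 CPM in KO (SD, n = 3), and Pdxk at 1595 ± 255 CPM in WT and 2492 ± 171 CPM in KO. Hspe1, a mitochondrial co-chaperonin, stood at 665 ± 29.9 CPM in WT and 519 ± 23.3 CPM in KO. In each of these 3 genes the KO replicates all lay on one side of the WT replicates. None of them passed the threshold in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gave adjusted p = 0.504 for Adamts4 and Pdxk and 0.927 for Hspe1. Of 1484 genes tested, 0 were higher and 0 were lower in KO at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 59 genes, 40 of them higher in KO, where 74.2 are expected by chance. DESeq2 on the same 6 replicates called 6 genes higher and 1 lower, and limma-voom called 0. Treating the 12 libraries as separate samples, edgeR called 31 genes higher and 18 lower and DESeq2 63 and 42, and limma-voom with the replicate as a block of correlated libraries called 7 higher. Adamts4, Pdxk, Cd244a, Lilr4b and Lilrb4a were among the genes that DESeq2 called higher in KO, but without KO replicate 2 DESeq2 called 0 genes, with adjusted p = 0.102 for Adamts4 and Pdxk and 0.999 for Cd244a, Lilr4b and Lilrb4a. The DESeq2 log2 fold change without that replicate was 0.515 for Adamts4 and 0.710 for Pdxk, against 0.524 and 0.655 with it, while that of Cd244a fell from 6.57 to 5.12, of Lilr4b from 3.35 to 2.14 and of Lilrb4a from 2.46 to 1.49. Adamts4 passed in the other 5 DESeq2 fits without a replicate (adjusted p from 4.43e-05 to 0.0264), and Pdxk in 3 of them. Adamts4 was named by a rule set before the data were examined, and the other genes of this paragraph were chosen after their values were seen.

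The fixed list of mature oligodendrocyte and myelin genes had 2 members among the genes tested, Adamts4 and Nfasc. Nfasc encodes neurofascin, an adhesion molecule of the paranodal junction and the node of Ranvier, and stood at 4788 ± 578 CPM in WT and 6434 ± 845 CPM in KO (SD, n = 3). The log2 fold changes, KO over WT, were 0.51 ± 0.11 (SE) for Adamts4 and 0.43 ± 0.14 for Nfasc. Both passed when adjusted over the list alone, and 0 passed when adjusted over all genes tested. As a set they ranked above the other genes (camera with the preset correlation, adjusted p = 1.01e-05), and adjusted p = 0.353 with an estimated correlation. Adamts4 lies on chromosome 1 from 171250129 to 171262267 in mm10, and Nfasc lies on chromosome 1 from 132564690 to 132741848. Whether counting used the strand is not given in the sources used here, so the values of genes that overlap others, Adamts4 included, are uncertain to that extent.

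**Figure D1:**
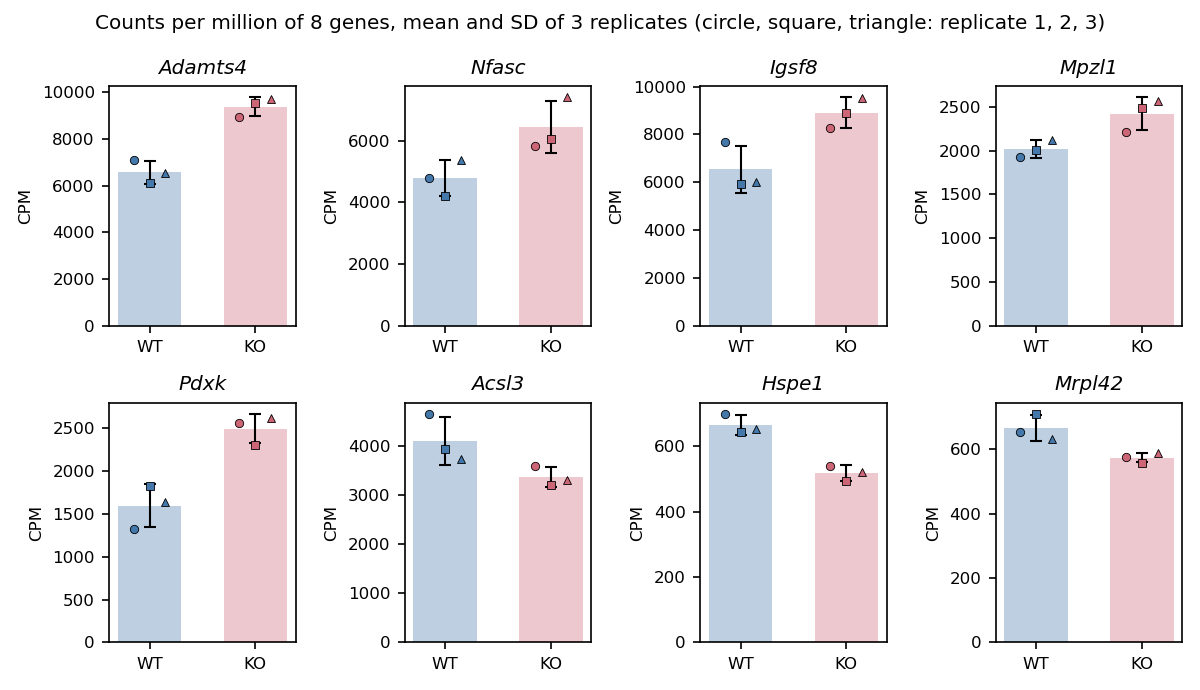
CPM of 8 genes in each biological replicate of WT and KO, with bars for the mean of 3 replicates and whiskers for the SD. The KO replicates of Adamts4 lie between 8944 and 9696 CPM and its WT replicates between 6116 and 7091 CPM, and none of the 8 genes had an edgeR adjusted p under 0.05.

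Differentiating oligodendrocyte genes had 5 members tested, all with a log2 fold change above 0 and a median of 0.26. Mpzl1, a receptor-like adhesion protein, stood at 2019 ± 102 CPM in WT and 2417 ± 188 CPM in KO (SD, n = 3). Zfp365 stood at 1958 ± 270 CPM in WT and 2051 ± 251 CPM in KO. No member passed the edgeR test, adjusted over all genes or adjusted over the list alone. The set ranked above the other genes with the preset correlation (camera adjusted p = 0.0144), and adjusted p = 0.565 with an estimated correlation. That call was lost without WT replicate 1 (adjusted p = 0.0645), without KO replicate 2 (0.0857) and without KO replicate 3 (0.239). Of the 37 oligodendrocyte progenitor genes only 2 were tested, and their sum lay between 0.497 and 27.9 CPM in the 6 replicates. Among them Tnr stood at 6.59 ± 5.97 CPM in WT and 11.8 ± 12.2 CPM in KO, and the list had a camera adjusted p of 0.219. These 2 genes do not speak for progenitor genes in general. The 12 genes of an added list of further progenitor and precursor genes summed to between 8174 and 9757 CPM. Of the disease-associated oligodendrocyte genes, Sgk1 stood at 29006 ± 17933 CPM in WT and 25401 ± 17861 CPM in KO, and Igfbp5 at 236 ± 83.4 CPM in WT and 254 ± 133 CPM in KO, with a camera adjusted p of 0.805.

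Cholesterol synthesis genes were represented by Lss, lanosterol synthase, at 667 ± 139 CPM in WT and 822 ± 178 CPM in KO, and by Hsd17b7 at 624 ± 62.5 CPM in WT and 719 ± 179 CPM in KO (SD, n = 3). In the list of fatty acid and sphingolipid synthesis, Acsl3, a long-chain acyl-CoA synthetase, stood at 4111 ± 487 CPM in WT and 3378 ± 200 CPM in KO, with every KO replicate below every WT replicate and an edgeR adjusted p of 0.994. Degs1, the desaturase that makes ceramide from dihydroceramide, stood at 11595 ± 1874 CPM in WT and 12273 ± 1806 CPM in KO. The camera adjusted p was 0.408 for both lists. The 9 nuclear-encoded subunits of the respiratory chain had a median log2 fold change of -0.05 and a camera adjusted p of 0.804. Ndufs7 stood at 3030.0 ± 206 CPM in WT and 2925 ± 252 CPM in KO. Among 4 genes of mitochondrial import, carriers and cristae, the phosphate carrier Slc25a3 stood at 1276 ± 158 CPM in WT and 1422 ± 84.9 CPM in KO, and Timm13 at 1246 ± 171 CPM in WT and 1249 ± 41.1 CPM in KO, with a camera adjusted p of 0.522.

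Genes of the nuclear lamina and envelope had 6 members tested, with a median log2 fold change of -0.06 and a camera adjusted p of 0.804. Lbr, the lamin B receptor that tethers heterochromatin to the inner nuclear membrane, stood at 1402 ± 21.8 CPM in WT and 1458 ± 208 CPM in KO (SD, n = 3). Tor1aip2, a torsin activator of the endoplasmic reticulum membrane, stood at 2107 ± 207 CPM in WT and 2032 ± 48.7 CPM in KO. The heterochromatin and Polycomb genes tested were Hdac2, at 826 ± 130 CPM in WT and 807 ± 30.5 CPM in KO, and Rnf2, at 321 ± 72.1 CPM in WT and 306 ± 14.7 CPM in KO. Among 5 genes of the p53 response and senescence, Phlda3 stood at 4345 ± 856 CPM in WT and 4406 ± 230 CPM in KO. Cell cycle genes stood at low levels, with Mcm3 at 112 ± 4.61 CPM in WT and 112 ± 13.2 CPM in KO, and Mcm6 at 89.6 ± 15.7 CPM in WT and 101 ± 15.8 CPM in KO. Of the cytosolic ribosomal proteins, Rpl7 stood at 1425 ± 165 CPM in WT and 1403 ± 114 CPM in KO, and Rpl37a at 1082 ± 97.6 CPM in WT and 1053 ± 183 CPM in KO. None of these lists passed the camera test, with adjusted p from 0.641 to 0.804.

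Genes of the immediate early response, which tissue dissociation can induce, varied more among replicates than between genotypes. Egr2 ranged from 78.5 to 1315 CPM in WT and from 49.8 to 930.4 CPM in KO, and Btg2 from 129.9 to 1855 CPM in WT and from 242 to 1173 CPM in KO. Their list had a median log2 fold change of -0.40 and a camera adjusted p of 0.641. In the list of ATF4 targets and the unfolded protein response, Ddit4 stood at 222 ± 110.3 CPM in WT and 137 ± 44.8 CPM in KO (SD, n = 3), and Atf3 at 132 ± 105 CPM in WT and 115 ± 86.4 CPM in KO, with a camera adjusted p of 0.408.

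Markers of other cell types gave the following levels beside these groups. The microglia and macrophage list had 2 members tested, Ptprc, which encodes CD45, and Fcer1g, a signalling subunit of Fc receptors. Ptprc stood at 17.0 ± 7.10 CPM in WT and 62.2 ± 45.7 CPM in KO (SD, n = 3), and Fcer1g at 44.8 ± 15.2 CPM in WT and 78.8 ± 52.9 CPM in KO. KO replicate 2 had the highest level of both, 106 CPM of Ptprc and 136 CPM of Fcer1g, while KO replicate 3 had 14.9 and 32.1 CPM. One of the 2 genes, Ptprc, passed when adjusted over the list alone and 0 passed over all genes tested. The camera adjusted p was 0.0448 with the preset correlation, and adjusted p = 0.838 with an estimated correlation. Without KO replicate 2 the adjusted p was 0.415. It was also above the threshold without WT replicate 1 (0.0799), WT replicate 2 (0.208), WT replicate 3 (0.179) or KO replicate 1 (0.116). Astrocyte genes stood at 253 ± 144 CPM in WT and 360.0 ± 326 CPM in KO for Gja1, and at 175 ± 115 CPM in WT and 302 ± 129 CPM in KO for Gpr37l1. Genes of mural cells and fibroblasts stood at 111.3 ± 79.6 CPM in WT and 170.2 ± 139 CPM in KO for Fn1, and at 106 ± 69.7 CPM in WT and 143 ± 34.7 CPM in KO for Dcn. Bsg, used by endothelial cells but also by other cells, stood at 3651 ± 756 CPM in WT and 3518 ± 584 CPM in KO. Of the neuronal genes, Scg2 stood at 86.5 ± 121 CPM in WT and 16.3 ± 17.7 CPM in KO, and Syt1 at 9.57 ± 10.5 CPM in WT and 6.47 ± 3.31 CPM in KO. Kcnj13, a potassium channel of the choroid plexus, stood at 131 CPM in WT replicate 1 and between 1.58 and 16.2 CPM in the other 5 replicates. The Schwann cell list had Cdh19 at 788 ± 119 CPM in WT and 798 ± 108 CPM in KO, and Egr2, given above as an immediate early gene. Whether these levels come from Schwann cells was not tested. Apart from the microglia and macrophage list, these lists did not pass the camera test, with adjusted p from 0.408 to 0.804.

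**Figure D2:**
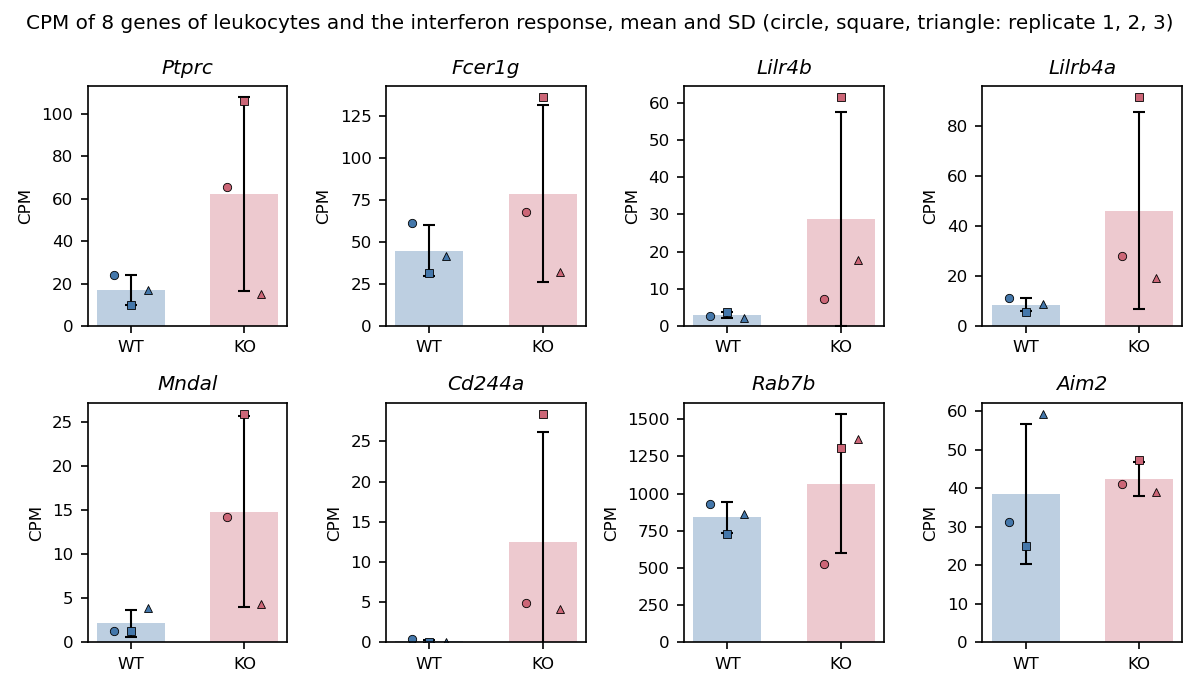
CPM of 8 genes of leukocytes and the interferon response in each biological replicate, with bars for the mean of 3 replicates and whiskers for the SD, cut at 0. KO replicate 2 is the highest of the 6 replicates in Ptprc, at 106 CPM, and in Fcer1g, Lilr4b, Lilrb4a, Mndal and Cd244a, but not in Rab7b and Aim2.

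**Figure D3:**
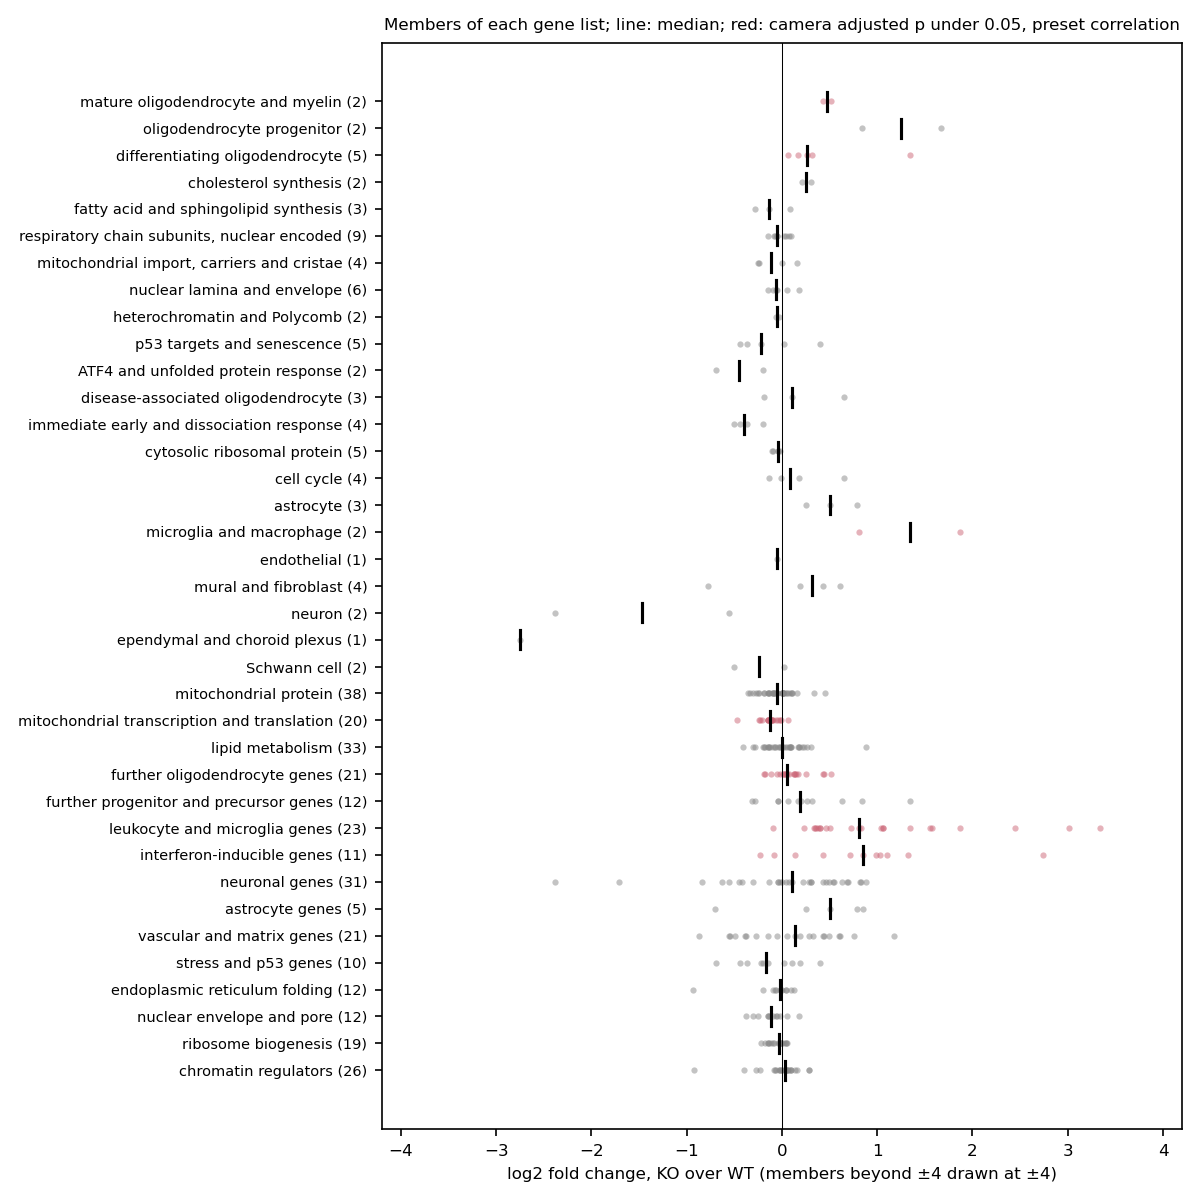
Log2 fold change, KO over WT, of each tested member of the gene lists, with the number of members in parentheses and a line at the median. Red lists had a camera adjusted p under 0.05 with the preset correlation, as in the 23 leukocyte and microglia genes with a median of 0.81, and none of them had one with an estimated correlation.

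The precision of 3 replicates against 3 left small changes hard to see. The median SE of a log2 fold change was 0.21 over the 1484 genes, and 63.6% of the genes had a 95% interval within 1 log2 unit of no change. In simulated data with the dispersion of these replicates, the edgeR test recovered 22.6% of genes changed by 1.5-fold, 55.2% of genes changed by 2-fold, 76.4% of genes changed by 4-fold and 87.4% of genes changed by 8-fold among 1484 genes. These shares hold for data in which 200 of the 1484 genes were changed. Recovery with fewer changed genes was not simulated. The replicates of the genotypes did not overlap in 126 genes, 8.49% of those tested, where chance gives 10% for 3 against 3.

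**Figure D4:**
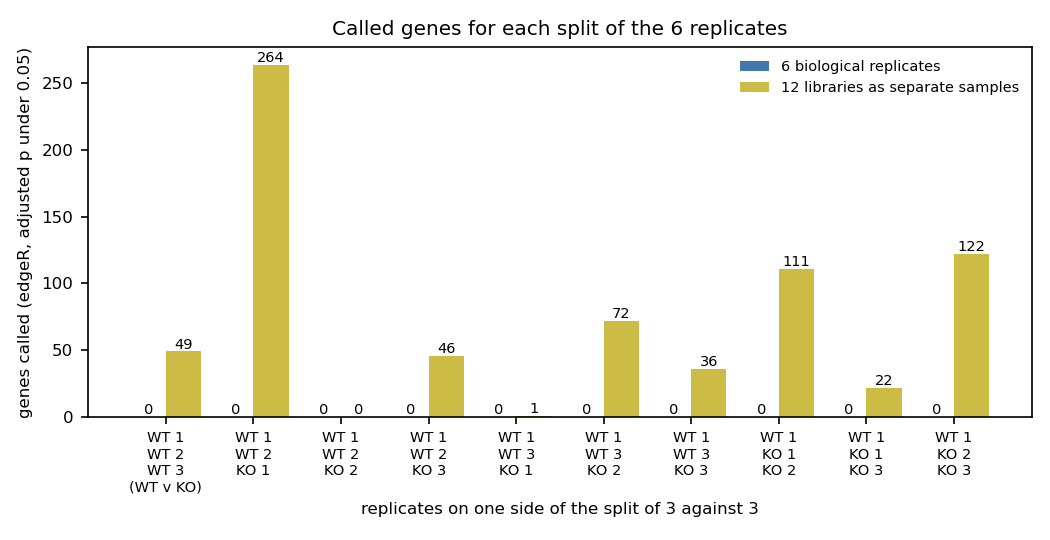
Genes called by edgeR at an adjusted p under 0.05 for each of the 10 splits of the 6 replicates, over 6 biological replicates or over 12 libraries as separate samples. Over 6 replicates every split called 0 genes, and over 12 libraries the WT against KO split called 49 and the highest other split 264.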

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

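The counts of 0 genes higher and 0 lower held under other size factors, other filters, limma-voom and the first or second library of each replicate alone. The same counts held with the vascular and matrix covariate (92 genes at an unadjusted p under 0.05) and in each of the 6 edgeR fits without a replicate (34 to 86 such genes). They moved to 6 higher and 1 lower with DESeq2 on the 6 replicates, to 9 and 4 with DESeq2 without WT replicate 1, 9 and 0 without WT replicate 2, 3 and 2 without WT replicate 3, 6 and 1 without KO replicate 1 and 11 and 2 without KO replicate 3, while DESeq2 without KO replicate 2 called 0 and 0. They also moved to 31 and 18 with edgeR and to 63 and 42 with DESeq2 on 12 separate libraries, and to 7 higher with duplicateCorrelation on 12 libraries. The edgeR and DESeq2 fits of 12 separate libraries treat the libraries of a replicate as independent by construction, and for the other changes the cause was not tested. The fits of Lmna and Cnp were not run because these genes are not analysed here. Same-numbered replicates of the genotypes had correlated deviations of -0.0032, -0.30 and 0.14 across genes, and WT replicate 2 correlated best with KO replicate 1 (0.35). These values gave no sign that the numbers pair the samples. With so few replicates they cannot exclude a shared litter or day. The replicate block left 0 genes higher and 0 lower, with 49 at an unadjusted p under 0.05. The covariate, DESeq2 on 12 libraries, DESeq2 without each replicate and the test of lists with at least 3 tested members were chosen after seeing the data, and the test of lists changed none of the 5 set calls it covers, while the mature oligodendrocyte and the microglia and macrophage lists have 2 tested members and are outside it. A fold threshold cannot change a count of 0. All 944 genes whose 95% interval lay within 1 log2 unit of no change had a mean count of at least 50, so no gene of lower count was measured that closely. Whether depth or the spread between replicates sets this limit was not tested.

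All 7 set calls, with medians of 0.47 for mature oligodendrocyte and myelin, 0.26 for differentiating oligodendrocyte, 1.34 for microglia and macrophage, -0.12 for mitochondrial transcription and translation, 0.050 for further oligodendrocyte genes, 0.81 for leukocyte and microglia genes and 0.85 for interferon-inducible genes, were lost with an estimated correlation (adjusted p from 0.353 to 0.838) and with fry (from 0.0573 to 0.875). The 7 calls are not independent, since lists share members. Fcer1g is in the microglia and macrophage list and in the leukocyte list. Adamts4 and Nfasc are in the mature and the further oligodendrocyte lists.

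With DESeq2 on 12 separate libraries, the sign changed for Mcm3 (0.0064), and a set call was gained for mitochondrial protein (median -0.046, adjusted p 0.0456) and further progenitor and precursor genes (median 0.20, adjusted p 0.0425). With edgeR on 12 separate libraries, the sign changed for disease-associated oligodendrocyte (-0.043) and Mcm3 (0.00069), and the set call was lost for microglia and macrophage (median 1.35, adjusted p 0.134), and a set call was gained for further progenitor and precursor genes (median 0.19, adjusted p 0.0431). With duplicateCorrelation on 12 libraries, the sign changed for heterochromatin and Polycomb (0.0025), disease-associated oligodendrocyte (-0.075), Hdac2 (0.0069) and Mcm3 (0.00036), and the set call was lost for microglia and macrophage (median 1.13, adjusted p 0.108) and interferon-inducible genes (median 0.55, adjusted p 0.116), and a set call was gained for further progenitor and precursor genes (median 0.20, adjusted p 0.00819). With DESeq2 on the 6 replicates, the sign changed for Mcm3 (0.0023). With the first library of each replicate alone, the sign changed for disease-associated oligodendrocyte (-0.046), Timm13 (-0.0092) and Mcm3 (0.035). With the second library of each replicate alone, the sign changed for disease-associated oligodendrocyte (-0.040), endoplasmic reticulum folding (0.0071) and Rpl7 (0.0096). With library size alone, the sign changed for lipid metabolism (-0.025), chromatin regulators (-0.0049), Timm13 (-0.026), Phlda3 (-0.0092) and Cdh19 (-0.015). With limma-voom, the sign changed for disease-associated oligodendrocyte (-0.17) and lipid metabolism (-0.00050), and the set call was lost for microglia and macrophage (median 1.12, adjusted p 0.348) and interferon-inducible genes (median 0.57, adjusted p 0.072). With a mean count of at least 50, the sign changed for disease-associated oligodendrocyte (-0.036) and Mcm3 (0.0036), and the set call was lost for interferon-inducible genes (median 0.45, adjusted p 0.446), and a set call was gained for further progenitor and precursor genes (median 0.20, adjusted p 0.0393) and neuronal genes (median 0.20, adjusted p 0.0393). With median-of-ratios factors, the sign changed for Mcm3 (0.0010). With the replicate block, the sign changed for disease-associated oligodendrocyte (-0.26), and the set call was lost for microglia and macrophage (median 1.07, adjusted p 0.0682), and a set call was gained for ependymal and choroid plexus (median -1.94, adjusted p 0.00528). With the vascular and matrix covariate, the sign changed for disease-associated oligodendrocyte (-0.31), immediate early and dissociation response (0.050), lipid metabolism (-0.027), Timm13 (-0.015), Phlda3 (-0.014), Btg2 (0.25), Atf3 (0.23), Igfbp5 (-0.16) and Syt1 (0.34), and the set call was lost for microglia and macrophage (median 1.28, adjusted p 0.131), and a set call was gained for oligodendrocyte progenitor (median 2.12, adjusted p 0.0319), mitochondrial protein (median -0.084, adjusted p 0.0407), further progenitor and precursor genes (median 0.22, adjusted p 0.0407) and neuronal genes (median 0.20, adjusted p 0.0421). The cause was not tested.

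Leaving out 1 replicate at a time ended a set call for differentiating oligodendrocyte 0.19 to 0.32, microglia and macrophage 0.70 to 1.76, further oligodendrocyte genes 0.026 to 0.11, interferon-inducible genes 0.17 to 1.37 and mitochondrial transcription and translation -0.16 to -0.062, given as the lowest and highest median over the 6 fits. It gave one for immediate early and dissociation response -1.04 to 0.49, mural and fibroblast -0.19 to 0.65, oligodendrocyte progenitor 0.72 to 2.87 and cholesterol synthesis 0.15 to 0.43, and turned the sign of the median for cytosolic ribosomal protein -0.14 to 0.019, endothelial -0.20 to 0.12, ependymal and choroid plexus -4.09 to 0.10, chromatin regulators -0.021 to 0.050, respiratory chain subunits, nuclear encoded -0.092 to 0.013, nuclear lamina and envelope -0.12 to 0.035, heterochromatin and Polycomb -0.15 to 0.12, endoplasmic reticulum folding -0.15 to 0.073, ribosome biogenesis -0.093 to 0.020, ATF4 and unfolded protein response -0.90 to 0.18, disease-associated oligodendrocyte -0.93 to 0.42, neuron -2.43 to 0.42, Schwann cell -0.62 to 0.24, lipid metabolism -0.045 to 0.046, vascular and matrix genes -0.30 to 0.29, stress and p53 genes -0.26 to 0.075, astrocyte -0.20 to 0.90, astrocyte genes -0.20 to 0.90 and cell cycle -0.25 to 0.20. A set call was also gained for vascular and matrix genes without WT replicate 2 (median 0.29, adjusted p 0.0463), mitochondrial protein without WT replicate 3 (median -0.093, adjusted p 0.0149), further progenitor and precursor genes without KO replicate 1 (median 0.22, adjusted p 0.0261), neuronal genes without KO replicate 1 (median 0.18, adjusted p 0.0408) and nuclear envelope and pore without KO replicate 1 (median -0.18, adjusted p 0.0403). The sign of a log2 fold change turned in at least 1 of these fits for Tnr -0.36 to 1.69, Zfp365 -0.024 to 0.18, Degs1 -0.039 to 0.18, Ndufs7 -0.12 to 0.0089, Timm13 -0.053 to 0.12, Tor1aip2 -0.11 to 0.032, Lbr -0.060 to 0.15, Hdac2 -0.11 to 0.11, Rnf2 -0.20 to 0.13, Phlda3 -0.057 to 0.19, Btg2 -1.15 to 0.71, Atf3 -0.94 to 0.59, Sgk1 -0.94 to 0.31, Igfbp5 -0.36 to 0.42, Egr2 -1.35 to 0.39, Rpl7 -0.10 to 0.049, Rpl37a -0.14 to 0.093, Mcm3 -0.095 to 0.071, Gja1 -0.56 to 0.90, Bsg -0.20 to 0.12, Fn1 -0.30 to 1.31, Dcn -0.016 to 0.89, Syt1 -1.04 to 0.88, Kcnj13 -4.09 to 0.10, Cdh19 -0.11 to 0.11, Rmnd1 -0.47 to 0.029, Tmeff2 -0.014 to 0.20 and Aim2 -0.087 to 0.60. None of these genes passed the threshold in those fits, and the cause was not tested.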

Other observations

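The test of microglia as the only source and the added gene lists were chosen after the symbols or values were seen, and the other tests before their results were known. Immune genes had the smallest camera p among the added lists at the preset correlation, but not with an estimated correlation or fry, where mitochondrial transcription and translation had it (adjusted p = 0.379 and 0.0573, against 0.492 and 0.652 for leukocyte genes). Of 23 leukocyte and microglia genes, 22 had a log2 fold change above 0, with a median of 0.81, 2 passed in edgeR when adjusted over the list alone and 0 over all genes. The camera adjusted p of that list was 1.27e-09 with the preset correlation, and adjusted p = 0.492 with an estimated correlation of 0.48 between these genes. The median was 0.18 without KO replicate 2 (adjusted p = 0.0027 with the preset correlation) and 0.44 without WT replicate 2. By replicate the median relative to the WT mean was 0.33, -0.29 and 0.0033 in WT replicates 1, 2 and 3. It was 0.53, 1.36 and 0.17 in KO replicates 1, 2 and 3, so KO replicate 3 lay below WT replicate 1. The summed level of the list, to which abundant genes add most, gave another order for KO replicate 1. Its sum was 1186 CPM, below the 1485 and 1389 CPM of WT replicates 1 and 3, although its median lay above those of all WT replicates. Lilr4b and Lilrb4a, neighbouring receptor genes of myeloid cells that may share reads, stood at 2.85 ± 0.800 and 8.46 ± 2.66 CPM in WT and at 28.7 ± 28.8 and 46.3 ± 39.6 CPM in KO (SD, n = 3), or 12.4 and 23.6 CPM without KO replicate 2. Among 11 interferon-inducible genes 9 were above 0, with a median of 0.85 (camera adjusted p = 0.0168, and adjusted p = 0.635 with an estimated correlation), led by Mndal at 2.18 ± 1.55 CPM in WT and 14.8 ± 10.8 CPM in KO, or 9.29 CPM without KO replicate 2. Without that replicate the median of the list was 0.17 (adjusted p = 0.522). The list of interferon genes fixed before the data is not reported here, so these values do not speak for an interferon response. Rab7b stood at 841 ± 103 CPM in WT and 1067 ± 469 CPM in KO, and Aim2 at 38.5 ± 18.2 CPM in WT and 42.4 ± 4.39 CPM in KO. Icos and Ctla4, receptors of activated T cells, had 0 counts in WT and 51 and 56 counts in KO over the 3 replicates, at least 16.96-fold and 18.62-fold higher against a floor of 3 counts over the group. The lower limits of the 95% counting interval were 13.3 and 14.7, and without KO replicate 2 the floor gave at least 13.6-fold and 10.8-fold, with lower limits of 10.3 and 7.96. Cd244a had 2 counts in WT and 216 in KO, but 179 of the 216 lay in KO replicate 2. The ratio was 108 with a 95% counting interval from 29.5 to 895, and without that replicate 31.5 with an interval from 8.14 to 270. These intervals hold counting error alone, not the spread between biological replicates. These genes were chosen after their values were seen.

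In 20 genes of mitochondrial transcription and translation, 19 had a log2 fold change below 0, with a median of -0.12, and 0 passed in edgeR over all genes or adjusted over the list alone. The camera adjusted p was 0.00996 with the preset correlation, and adjusted p = 0.379 with an estimated correlation. Mrpl42, a mitochondrial ribosomal protein, stood at 666 ± 39.7 CPM in WT and 574 ± 14.6 CPM in KO (SD, n = 3), and Rmnd1 at 612 ± 175 CPM in WT and 521 ± 140 CPM in KO. Of 21 further oligodendrocyte genes, which hold Adamts4 and Nfasc again, 16 were above 0, with a median of 0.05 (camera adjusted p = 0.00996, and adjusted p = 0.492 with an estimated correlation). Igsf8, a tetraspanin partner at the cell surface, stood at 6541 ± 977 CPM in WT and 8901 ± 644 CPM in KO, while Tmeff2 stood at 18857 ± 3058 CPM in WT and 19528 ± 732 CPM in KO. Without KO replicate 2 the adjusted p of the mitochondrial list was 0.0687, and without KO replicate 3 that of the oligodendrocyte list was 0.304. Neu2 stood at 0.127 ± 0.219 CPM in WT and 3.03 ± 0.584 CPM in KO, and Inhbb at 0.416 ± 0.207 CPM in WT and 4.23 ± 1.81 CPM in KO. The other 11 added lists did not pass in this fit, although further progenitor and precursor genes passed in 6 of 22 other settings, mitochondrial protein and neuronal genes in 3 each, and vascular and matrix genes and nuclear envelope and pore in 1 each. In the fit of 6 replicates their camera adjusted p was 0.126 for mitochondrial protein, 0.894 for lipid metabolism, 0.0769 for progenitor and precursor genes, 0.159 for neuronal, 0.705 for astrocyte, 0.286 for vascular and matrix, 0.435 for stress and p53, 0.681 for endoplasmic reticulum folding, 0.143 for nuclear envelope and pore, 0.286 for ribosome biogenesis and 0.894 for chromatin regulators. The test direction was opposite to the median in the lists of disease-associated oligodendrocyte genes, lipid metabolism and chromatin regulators, none of which passed.

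The first pattern weighed is the higher level of leukocyte genes in KO. T or NK cells that passed the sort for GFP are a candidate source, and 15 genes of those cells, none in the list above, were summed. The sum was 18.2 ± 3.72 CPM in WT and 32.6 ± 23.2 CPM in KO (SD, n = 3), a ratio of 1.786, but KO replicate 1 at 15.4 CPM lay below all WT replicates and KO replicate 2 reached 58.9 CPM. The most abundant were Gzmm, Slamf7 and Ptpn7, with 41, 57 and 55 counts in KO replicate 2, and 4 of the 15 had counts in every replicate. Gzmm did not rise with the sum, at 41, 20 and 65 counts in WT replicates 1, 2 and 3 and 31, 41 and 43 in the KO replicates. It gave 31 of the 54 counts of KO replicate 1. Microglia as the only source would leave T and NK cell genes at the WT level, and the fold of T and NK cell genes over the WT mean, divided by that of 8 myeloid genes, all of them in the leukocyte list, ranged from 0.8734 in KO replicate 1 to 1.74 in KO replicate 2. The myeloid fold was 0.97, 1.86 and 1.06 in KO replicates 1, 2 and 3, and the T and NK cell fold 0.84, 3.23 and 1.28. Only KO replicate 2 thus had a marked myeloid excess to weigh. Neither test settles the source, since KO replicate 2 carries most of the difference in both sums. Icos and Ctla4, chosen after their values were seen, are not among the 15 genes. Icos had 16, 27 and 8 counts and Ctla4 7, 37 and 12 in KO replicates 1, 2 and 3, and both had 0 in WT. These low counts do not decide the source either, and a response of the brain to the genotype stays open and untested.

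The second pattern is the 31 higher and 18 lower genes that edgeR called when all 12 libraries were treated as separate samples, where the 6 replicates gave 0. If libraries of a replicate counted as independent were the cause, other splits of the 6 replicates would call as many genes. Of the 10 splits, 5 called at least 49 genes over 12 libraries, the real one included, and the highest other split called 264. That split put WT replicates 1 and 2 with KO replicate 1, and it points to a structure among the replicates that the genotype does not follow. These values go with repeated libraries as the cause of the calls, and they leave open which of the 49 genes also differ between genotypes at the level of biological replicates.

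The third pattern is the lower level of mitochondrial transcription and translation genes. Transcript length and expression level as a cause predict that matched random lists lie as low. Of 10000 lists of 19 genes matched on both, 4.49% had a median at or below -0.12, and the matched lists had a median of -0.03. The share counts low medians only, the direction in which this list had already been called. It therefore cannot decide whether these properties are the whole cause. A difference between genotypes and a difference between the 6 biological replicates apart from genotype stay open and untested.

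The 6 replicates can be split 3 against 3 in 10 ways, too few for a share under 0.05, so the splits cannot exclude chance for any result here. All 10 splits called 0 genes in 6 replicates, as the real one did, and the highest other was 0. In an exact enumeration of the splits, a camera p as small as the real one came from 1 split, the real one, for leukocyte genes (p = 8.46e-11, smallest other 3.62e-09), mitochondrial transcription and translation (0.00142, smallest other 0.0342), differentiating oligodendrocyte (0.00125, smallest other 0.0149), further oligodendrocyte (0.00199, smallest other 0.0155) and mature oligodendrocyte genes (4.4e-07, smallest other 0.037). In the same exact enumeration it came from 4 splits for interferon-inducible genes (0.00448, smallest other 5.74e-08) and from 3 for microglia and macrophage genes (0.00584, smallest other 7.62e-06). For leukocyte genes the camera p of the other splits ran from 3.62e-09 to 0.0813. Only the split of WT replicate 1 with KO replicates 1 and 3 lay above 0.05. A small camera p of that list at the preset correlation therefore did not require the split by genotype.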
